A study of Mus musculus with 12 samples.

How the data were processed

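RNA from 12 cultures of the mouse cell line Ocy454 was measured by sequencing of polyadenylated RNA, in 4 groups of 3 libraries that combined BGJ398 (200 nM) or DMSO with FGF2 (2 ng/mL) or control medium for 48 h after 1 h of pretreatment. Groups and replicate numbers came from the sample titles. The labels say only that each condition was run in triplicate, so the p-values measure the spread between these libraries, which may be partly technical. All pairs of libraries within a group differed by more than counting noise, with ratios to the Poisson expectation of 3.26 to 25.5, and none was treated as a duplicate.

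Reads were quantified per transcript with Salmon, per the submitters' processing notes, which give no version and name genome build GRCm39. The trimming, library type, use of strand and bias options are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Per the file headers, the deposited values are expected counts, abundances as TPM and effective lengths for each of 116178 transcripts. The expected counts are estimated reads per transcript and are not scaled. TPM are transcript counts corrected for length and scaled to a fixed total within each library before deposit. Effective lengths are in bases. The expected counts were summed per gene and rounded to whole numbers before testing, and TPM with the effective lengths entered only an alternative. Gene names and types came from the GENCODE M21 annotation (build GRCm38) by transcript identifier, which matched 114656 transcripts of 35214 genes. Another 1522 transcripts had no match there, and their reads, 0.499% to 0.641% of a library, stayed out of library sizes and tests. For 36 symbols shared by several identifiers the one with the most reads kept the plain symbol. The others stayed in the data under the symbol with their identifier. No coordinates are given, because that annotation is of another build than the files.

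Depth was 18951710 to 27716975 reads per library, and mitochondrially encoded genes took 1.70% to 2.11% of them. Tests used edgeR 4.0.16 (R 4.3.3) with filterByExpr by group, which kept 12542 genes, TMM scaling and the quasi-likelihood test on 1 model of the 4 group means over all 12 libraries, with 8 residual degrees of freedom. The biological coefficient of variation was 8.49%. Adjusted p-values are Benjamini-Hochberg values from edgeR, with a threshold of 0.05, and the error of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM are means over 3 libraries. The comparisons were FGF2 in DMSO, FGF2 under BGJ398, BGJ398 without FGF2, BGJ398 with FGF2, and the interaction, which is the FGF2 change under BGJ398 minus that in DMSO. All tests are 2-sided.

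The groups, tests, thresholds, named-gene rule, gene lists and the first group of other settings given below were fixed before the data were examined. In each comparison the rule took the 10 highest and 10 lowest log2 fold changes (5 and 5 for FGF2 under BGJ398, BGJ398 with FGF2 and the interaction) among called protein-coding genes with a mean of at least 5 CPM, an assigned symbol and, outside the interaction, libraries that did not overlap between groups. It also took up to 4 called members of each list with the smallest p, any member printed as not past the test, and 16 genes of FGF signaling, osteocytes and osteoblasts whatever their test. The 32 lists covered FGF and ERK feedback, FGF receptors and ligands, osteoblast, osteocyte and mineralization genes, fibrillar collagens, matrix glycoproteins, basement membrane, integrins, focal adhesion, matrix proteases, cell-cell adhesion, apoptosis, p53, proliferation, Wnt, BMP and TGF-beta, YAP and SRF, osteoclast regulators, axon guidance, interferon, unfolded protein response, glycolysis and hypoxia, cholesterol, oxidative stress, mitochondrially encoded genes, and adipocyte, chondrocyte, muscle, tendon, macrophage and endothelial markers. The 27 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation kept 2, 0, 2, 2 and 2 of the 11, 2, 8, 12 and 11 lists called in the comparisons above, in that order. By fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 17, 0, 4, 22 and 11 lists passed.

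The procedure was tested on simulated counts drawn from the means and library sizes of these genes with 100 genes changed at each fold. All simulations gave the groups the same spread for a gene and drew genes independently, so they leave out deviations that libraries share. The edgeR test recovered 76% of genes changed 1.5-fold and 87% of those changed 2-fold for FGF2 in DMSO (12380 genes tested), 72% and 88% for FGF2 under BGJ398 (12377), 79% and 85% for BGJ398 alone (12379), 71% and 87% for BGJ398 with FGF2 (12375), and 49% and 84% for the interaction (12391). A simulated slope of 0.4 came out as 0.365. Correlations between comparisons that share libraries were set beside 20 simulations with no effect. The error of a slope is a jackknife over the 12 libraries.

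Each comparison was also tested with RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, length-scaled TPM, the replicate number as a block, protein-coding genes only, the compared groups alone, stricter thresholds, camera with an estimated correlation, fry, and leaving out each library in turn. Settings added after the data were seen were offsets for gene length and GC content (mgcv 1.9.3), the first axis of the within-group deviations of 5000 genes as a covariate, leaving out 3 libraries that deviated together along that axis (BGJ398 replicate 1, DMSO+FGF2 replicate 2 and BGJ398+FGF2 replicate 2), leaving out genes with near-identical copies, and both inhibitor groups together. A gene was taken to have near-identical copies, and its counts as uncertain, when it shared at least 50% of its 31-base sequences with another gene. This held for 655 tested genes, among them 32 of the 1680 called for FGF2, 1 of the 41 for BGJ398 alone, 104 of the 2782 for BGJ398 with FGF2 and 10 of the 532 for the interaction. Gene properties and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.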

Results

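The transcriptome of Ocy454 cells, a mouse osteocyte-like cell line, was compared with and without fibroblast growth factor 2 (FGF2) in the presence or absence of BGJ398, a small-molecule inhibitor of the FGF receptor kinases. The cells had differentiated for 5 days before they were pretreated for 1 h with 200 nM BGJ398 or with its vehicle DMSO, and were then treated for 48 h with 2 ng/mL FGF2 or with control medium. Polyadenylated RNA was sequenced on differentiation day 7 from 4 groups of 3 libraries, named here DMSO, DMSO+FGF2, BGJ398 and BGJ398+FGF2. Depth ranged from 18951710 to 27716975 reads per library, and 12103 to 12470 genes had at least 10 reads in a library. The first principal component of log2 read counts scaled to library size (CPM) held 26.4% of the variance, and the 3 DMSO+FGF2 libraries lay at 24.0 to 33.7 on it, apart from the other 9 libraries, which lay at −19.7 to 0.70.

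The first comparison asked what FGF2 changed in these maturing cells when its receptors were not inhibited. Genes of the mineralizing osteoblast fell. Alpl (ENSMUSG00000028766), the alkaline phosphatase that frees phosphate for mineral, averaged 12.02 ± 0.32 CPM (SD, n = 3) in DMSO and 1.32 ± 0.24 CPM (SD, n = 3) in DMSO+FGF2, a 9.03-fold decrease with a log2 fold change of −3.18 ± 0.13 (SE, adjusted p = 8.69e-09). Eln (ENSMUSG00000029675), which encodes elastin, fell from 14.4 ± 2.1 to 1.15 ± 0.33 CPM, a 12.6-fold decrease with a log2 fold change of −3.66 ± 0.23 (SE, adjusted p = 3.56e-07). Postn (ENSMUSG00000027750), the matrix protein periostin, fell 2.91-fold from a mean of 266 to 91.4 CPM, and Npnt, a matrix ligand of integrins, fell 3.72-fold from 427 to 115 CPM. Tnfrsf9 (ENSMUSG00000028965), a receptor of the tumor necrosis factor family, rose 3.72-fold from 32.4 to 121 CPM, and Car9, a carbonic anhydrase induced by hypoxia, rose 2.86-fold from 222 to 635 CPM.

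Of the 18 tested genes in the osteoblast list, 12 fell and 1 rose with FGF2, or 13 and 1 when adjusted over the list alone (camera adjusted p = 7.28e-18). The homeobox factor Dlx5 changed by −1.28 ± 0.09 on the log2 scale (SE), Sparc, the collagen-binding protein osteonectin, by −0.70 ± 0.05, and the main bone collagen gene Col1a1 by −0.68 ± 0.09. Spp1, which encodes the mineral-binding phosphoprotein osteopontin, was the member that rose, 2.54-fold from 377 to 957 CPM. Ibsp, bone sialoprotein, averaged 1.01 CPM in DMSO and 0.0142 CPM in DMSO+FGF2. Bglap, osteocalcin, changed by −1.41 ± 0.41 (adjusted p = 0.0371) on 167 reads over the 12 libraries, shared 62.9% of its 31-base sequences with other genes and is uncertain. Among 13 mineralization and phosphate genes 5 rose and 3 fell, or 6 and 4 when adjusted over the list alone. Enpp1, which makes the mineral inhibitor pyrophosphate, rose by 1.03 ± 0.08. That list's median was 0.16 and its mean −0.48, the test direction was up, and its adjusted p was 0.232.

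Many extracellular matrix genes fell. Among 29 matrix glycoproteins and proteoglycans 16 fell and 3 rose, or 16 and 4 when adjusted over the list alone (adjusted p = 1.9e-26). The small leucine-rich proteoglycans Fmod and Aspn changed by −1.08 ± 0.05 and −1.54 ± 0.09, and tenascin C, Tnc, by −1.40 ± 0.08. Of 28 fibrillar collagens and collagen-processing genes 13 fell and 3 rose, or 14 and 4 over the list alone, including Col11a1 at −1.38 ± 0.09, Col12a1 at −1.27 ± 0.13 and Col3a1 at −0.59 ± 0.06. This list had an adjusted p of 3.04e-09 (adjusted p = 0.170 with an estimated correlation). Of 19 basement membrane genes 8 fell and 2 rose, or 10 and 2 over the list alone, with the collagen IV chains Col4a1 and Col4a2 at −0.79 ± 0.08 and −0.85 ± 0.08 (adjusted p = 5.04e-06; adjusted p = 0.181 with an estimated correlation). The osteoblast and glycoprotein lists stayed past the threshold with an estimated correlation, at adjusted p = 0.000525 and 4.48e-05. The integrins did not move one way: 6 of 17 rose and 3 fell (6 and 4 over the list alone; adjusted p = 0.689), with the collagen receptor subunits Itga1 and Itga11 at −1.01 ± 0.09 and −0.56 ± 0.06 and Itga6 at 0.46 ± 0.08.

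**Figure D1:**
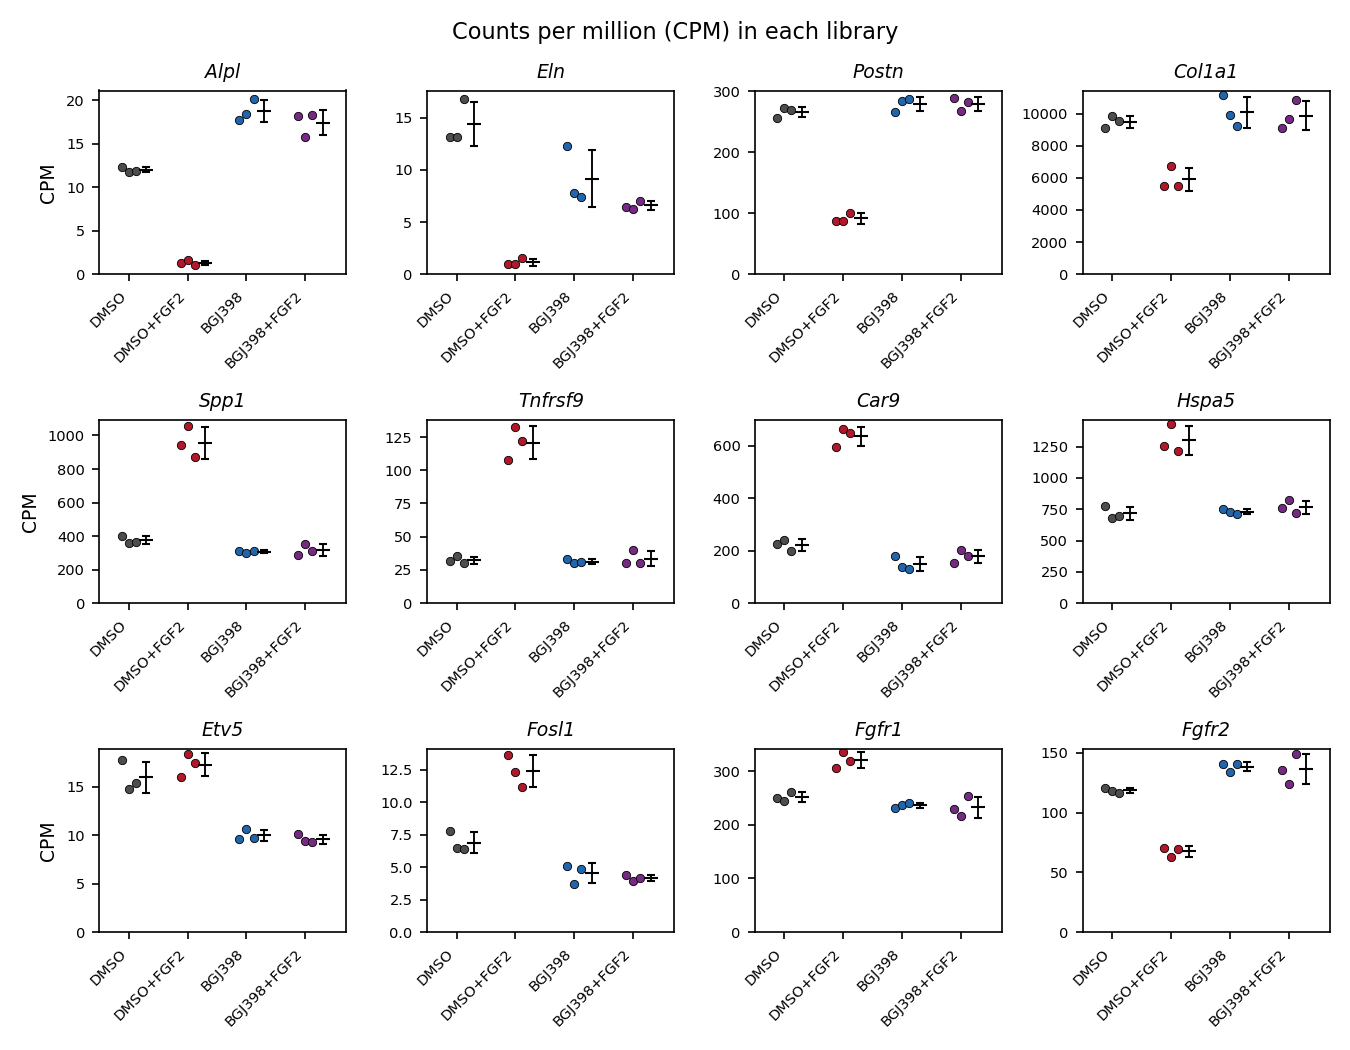
CPM of 12 genes in the 4 groups, with each library as a point and the mean and SD of 3 libraries as bars. Mean Alpl was 12.02 CPM in DMSO, 1.32 in DMSO+FGF2, 18.8 in BGJ398 and 17.4 in BGJ398+FGF2.

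Chaperones and glycolytic enzymes were higher with FGF2. In the unfolded protein response list 14 of 23 genes rose and 1 fell, or 17 and 1 when adjusted over the list alone (adjusted p = 3.06e-19; adjusted p = 0.0769 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 719 to 1300 CPM, a log2 fold change of 0.85 ± 0.07, and its partners Sdf2l1, Creld2 and Pdia4 rose by 1.46 ± 0.12, 1.13 ± 0.10 and 0.76 ± 0.05. In the glycolysis and hypoxia list 20 of 26 genes rose and 0 fell, or 23 and 0 when adjusted over the list alone (adjusted p = 3.12e-17; adjusted p = 0.170 with an estimated correlation). The glycolytic genes Gpi1 and Gapdh rose by 0.73 ± 0.10 and 0.73 ± 0.11, and the hypoxia-induced Ndrg1 by 0.82 ± 0.09.

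Lists of growth and matrix-responsive signaling were lower. Of 19 targets of the transcription factors YAP and SRF 11 fell and 2 rose, or 11 and 3 over the list alone, with tissue factor F3 at −0.59 ± 0.06, connective tissue growth factor Ccn2 at −0.76 ± 0.11 and smooth muscle actin Acta2 at −0.56 ± 0.08 (adjusted p = 5.39e-05; adjusted p = 0.170 with an estimated correlation). Of 21 BMP and TGF-beta response genes 9 fell and 3 rose, or 9 and 5 over the list alone, among them Tgfb3 at −0.74 ± 0.06 and Id3 at −0.74 ± 0.09, with the activin subunit Inhbb at 1.33 ± 0.15 (adjusted p = 0.00679; adjusted p = 0.207 with an estimated correlation). Of 28 proliferation genes 6 fell and 0 rose (8 and 0 over the list alone), with cyclin A2, Ccna2, at −0.28 ± 0.05. This list had an adjusted p of 0.0166, which became 0.0564 without DMSO+FGF2 replicate 3 (adjusted p = 0.207 with an estimated correlation). In the cholesterol synthesis list 5 of 23 genes fell and 0 rose, the same counts over the list alone (adjusted p = 0.00544; adjusted p = 0.247 with an estimated correlation).

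The receptor list was lower as well, with 4 of 15 genes lower and 1 higher, or 8 and 1 over the list alone (adjusted p = 0.00986; adjusted p = 0.207 with an estimated correlation). Fgfr2 changed by −0.81 ± 0.07 and Fgfr1 by 0.35 ± 0.06, while Fgfr3 had −0.22 ± 0.10 (adjusted p = 0.151). The FGF and ERK feedback list was not called, with 4 of 20 genes higher and 3 lower, or 5 and 3 over the list alone (adjusted p = 0.118). The ERK phosphatase gene Dusp4 rose by 1.09 ± 0.15 and Ier3 by 0.66 ± 0.09, while Myc changed by −0.39 ± 0.05 and cyclin D1, Ccnd1, by −0.49 ± 0.07. The common readouts of FGF receptor signaling Dusp6, Spry4, Etv4 and Etv5 did not pass the test after 48 h of FGF2. Dusp6 had a log2 fold change of 0.25 ± 0.12 (adjusted p = 0.227, or 0.0451 without DMSO replicate 1), Spry4 one of 0.42 ± 0.32, Etv4 one of 0.27 ± 0.22 and Etv5 one of 0.12 ± 0.09.

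Other lists fixed beforehand were not called. Osteocyte genes had 2 of 10 higher and 3 lower (the same over the list alone; adjusted p = 0.262), with the early osteocyte marker Pdpn at 0.52 ± 0.08 and Irx5 at −0.62 ± 0.09. The late osteocyte genes were at or near 0: Sost and Mepe had 0 reads in the 12 libraries, Dmp1 had 26 and Fgf23 had 6. Phex had −0.36 ± 0.43 (adjusted p = 0.65). Focal adhesion and actin genes had 6 of 29 higher and 4 lower, matrix proteases and inhibitors 6 of 25 higher and 5 lower, and cell-cell adhesion genes 5 of 19 higher and 5 lower, with N-cadherin, Cdh2, at −0.48 ± 0.06. Over those lists alone the counts were 8 and 5, 6 and 6, and 5 and 6. Of 25 apoptosis regulators 3 rose and 1 fell (3 and 2 over the list alone; adjusted p = 0.141), with Casp12, a caspase of the endoplasmic reticulum, at 0.45 ± 0.06. Of 18 p53 targets 2 rose and 1 fell (3 and 1 over the list alone), with the kinase gene Plk2 at −0.58 ± 0.05.

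Wnt pathway genes had 3 of 21 higher and 5 lower (4 and 7 over the list alone), with Ccn5 at 1.18 ± 0.12 and the Wnt antagonist Sfrp2 at −0.63 ± 0.07. Osteoclast regulators and cytokines had 6 of 23 higher and 5 lower (8 and 5 over the list alone), with Igf1 at −1.24 ± 0.13 and Il34, a ligand of the macrophage growth factor receptor, at 0.84 ± 0.11. Axon guidance genes had 4 of 27 higher and 9 lower (5 and 10 over the list alone), with Sema7a at 1.65 ± 0.12 and Slit3 at −1.64 ± 0.13. Interferon-stimulated genes had 4 of 23 higher and 1 lower (7 and 1 over the list alone; adjusted p = 0.0516), with the nucleic acid sensor Zbp1 at 1.79 ± 0.18. Of 21 oxidative stress genes 2 rose and 0 fell, the metallothioneins Mt1 and Mt2, and 0 of 13 mitochondrially encoded genes passed the test, with the same counts over the list alone. Median and mean or test direction differed in sign for the focal adhesion, p53, Wnt and mitochondrial lists, whose adjusted p were 0.839, 0.906, 0.718 and 0.906.

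Markers of other cell types were few. Of 5 tested chondrocyte genes Sox9 rose by 0.84 ± 0.11 and Matn3 changed by −1.80 ± 0.16 (1 and 2 over the list alone; adjusted p = 0.153). The remaining lists had too few tested genes for a list test: 0 of 3 adipocyte, 0 of 3 muscle and 0 of 2 endothelial genes passed, while 2 of 4 tendon genes, Fmod and Egr1, fell and 1 of 3 macrophage genes, Cd68, rose.

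In all, 1680 of 12542 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 950 higher and 730 lower with FGF2, and 176 changed at least 2-fold, 88 in each direction. The 3 libraries of each group did not overlap for 4715 genes, 37.6% against the 10% chance gives. By camera 11 of 27 lists were called, 2 higher and 9 lower. The count was 1052 genes without DMSO replicate 2, 1018 without DMSO replicate 3 and 1086 without DMSO+FGF2 replicate 2, and 2611 without 3 libraries that deviated together from their groups, which were picked after the data were seen. It was 2670 with offsets for gene length and GC content and 3373 with the axis of within-group deviations as a covariate. That axis was taken from the residuals of these same libraries, so fitting it raises the count of any comparison by construction.

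**Figure D2:**
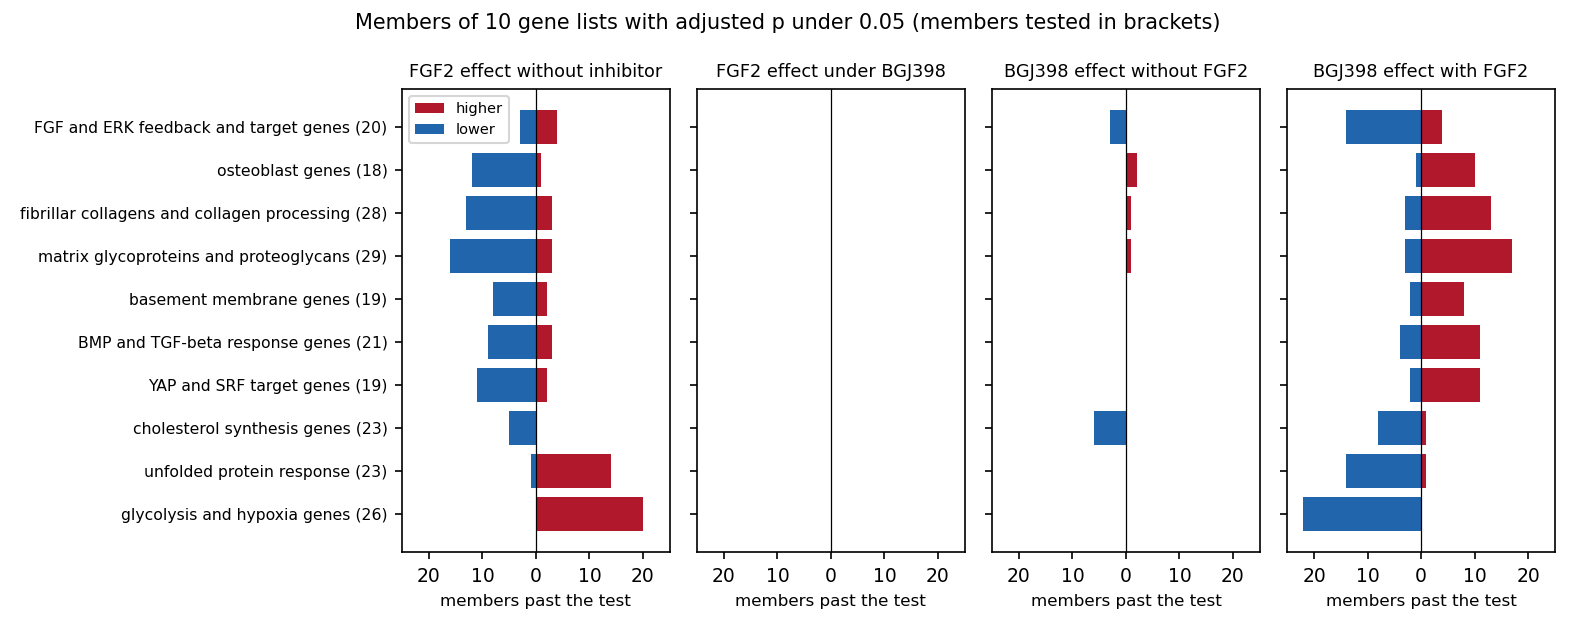
Numbers of genes past the test in each of 10 gene lists in 4 comparisons, with higher genes to the right and lower genes to the left of 0. Of 29 matrix glycoprotein genes 16 were lower with FGF2 alone and 17 were higher when BGJ398 was added to FGF2.

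The second comparison asked whether FGF2 still acted when its receptors were inhibited. Under BGJ398 none of the genes named above passed the test. Alpl averaged 18.8 ± 1.3 CPM in BGJ398 and 17.4 ± 1.4 CPM in BGJ398+FGF2 (SD, n = 3), a log2 fold change of −0.11 ± 0.10. The log2 fold changes of Spp1 and Col1a1 were 0.04 ± 0.08 and −0.03 ± 0.09, those of Tnfrsf9 and Hspa5 0.09 ± 0.11 and 0.07 ± 0.07, and those of Eln and Car9 −0.47 ± 0.19 and 0.26 ± 0.12. Postn averaged 279 CPM in BGJ398 and 280 CPM in BGJ398+FGF2. By edgeR 0 of 12542 genes were called, the smallest adjusted p was 0.194, and 325 genes (2.59%) had an unadjusted p under 0.05. DESeq2 called 5 genes and limma-voom 0. The count was 1 without BGJ398 replicate 2 and 1 without BGJ398 replicate 3, 4 without the 3 libraries that deviated together, and the groups did not overlap for 792 genes, 6.31% against the 10% chance gives. In simulated data 72% of genes changed 1.5-fold and 88% of those changed 2-fold were recovered in this comparison. The simulation gave all groups the same spread. Real ratios to the Poisson expectation reached 14.6 within BGJ398 and 25.5 within BGJ398+FGF2, beside 6.10 within DMSO, so real recovery may be lower.

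Glycolysis and hypoxia genes were called higher as a list (median log2 fold change 0.14, adjusted p = 6.06e-06; adjusted p = 0.728 with an estimated correlation) with 0 of 26 members past the test, over the list alone as well. Mitochondrially encoded genes were also called higher (median 0.12, adjusted p = 0.000922; adjusted p = 0.578 with an estimated correlation) with 0 of 13 members past it and 1 when adjusted over the list alone. Without BGJ398+FGF2 replicate 2 neither list was called. The glycolysis list was also lost without BGJ398 replicate 3, and the mitochondrial list without BGJ398 replicate 1, without BGJ398+FGF2 replicate 1, without the 3 libraries that deviated together and from length-scaled TPM. Without BGJ398+FGF2 replicate 3, 3 lists were called higher and 3 lower, in place of 2 and 0.

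The difference between these responses to FGF2 was tested as an interaction, for which a positive value means a more positive FGF2 change under BGJ398. The bone and matrix genes that FGF2 lowered led the positive side. Eln had an interaction of 3.19 ± 0.31, Alpl 3.07 ± 0.16, Pappa2, a protease that releases insulin-like growth factors, 1.95 ± 0.17, Npnt 1.82 ± 0.12 and the collagen gene Col27a1 1.65 ± 0.22. On the negative side were Tnfrsf9 at −1.80 ± 0.16, Sema7a, a membrane-bound semaphorin, at −1.78 ± 0.17, Hmga1, which shares 62.1% of its 31-base sequences with other genes and is uncertain, at −1.48 ± 0.13, the surface protein mesothelin, Msln, at −1.39 ± 0.12 and the deaminase gene Cda at −1.38 ± 0.20. The FGF2 readouts Dusp6 (−0.36 ± 0.18), Etv5 (−0.17 ± 0.13), Etv4 (−0.52 ± 0.33) and Spry4 (−0.10 ± 0.53) did not pass.

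The interaction was past the threshold for 532 genes, 250 positive and 282 negative, of which 108 differed at least 2-fold. Of these, 523 were also called for FGF2 alone, and all 523 had the opposite sign there. Because the interaction subtracts the FGF2 change in DMSO, the opposite signs follow in part from its construction. By list, osteoblast genes had 8 positive and 1 negative of 18 (10 and 1 over the list alone; adjusted p = 0.000664 with an estimated correlation), and matrix glycoproteins 14 and 2 of 29 (16 and 3 over the list alone; adjusted p = 5.48e-05 with an estimated correlation).

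Another 9 lists were called in the interaction with the preset correlation only. The unfolded protein response genes, with Hspa5 at −0.79 ± 0.10, had 1 positive and 9 negative (1 and 14 over the list alone; adjusted p = 0.137 with an estimated correlation), and glycolysis genes, with Car9 at −1.26 ± 0.17, 0 and 4 (0 and 8; adjusted p = 0.263 with an estimated correlation). Fibrillar collagens, with Col11a1 at 1.28 ± 0.12, had 12 and 0 (13 and 4; adjusted p = 0.234 with an estimated correlation), basement membrane genes 6 and 1 (8 and 2; adjusted p = 0.263 with an estimated correlation) and YAP and SRF targets 6 and 1 (10 and 2; adjusted p = 0.260 with an estimated correlation). BMP and TGF-beta response genes had 6 and 3 (9 and 4; adjusted p = 0.263 with an estimated correlation) and were at adjusted p = 0.0524 without BGJ398+FGF2 replicate 3. The FGF receptor list had 2 and 1 (5 and 1; adjusted p = 0.234 with an estimated correlation), with Fgfr2 at 0.79 ± 0.10, and proliferation genes 1 and 0 (2 and 0; adjusted p = 0.263 with an estimated correlation). Interferon-stimulated genes had 0 and 1 (1 and 5; adjusted p = 0.363 with an estimated correlation) and were at adjusted p = 0.0573 without DMSO+FGF2 replicate 2 and 0.112 without BGJ398+FGF2 replicate 3. The interaction count was 328 genes without DMSO replicate 2, 337 without DMSO replicate 3 and 956 without BGJ398+FGF2 replicate 2. It was 825 by DESeq2, 347 from length-scaled TPM, 1235 with length and GC offsets, 1642 with the within-group axis as a covariate and 1038 without the 3 libraries that deviated together.

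Over the 1680 genes called for FGF2, the slope of the FGF2 change under BGJ398 on that without it was 0.0450, with a jackknife SE of 0.122 and a range of −0.0700 to 0.0596 when each library was left out in turn. Across all tested genes, which are not independent replicates, the correlation of these changes was −0.0480, beside −0.0207 ± 0.0806 (SD) in simulated data with no effect, and the covariance −0.00634 beside −0.000948 ± 0.00448. Without genes that have near-identical copies, a set chosen after the values were seen, the correlation was 0.0735 beside −0.00579 ± 0.0479 and the covariance 0.00446 beside −0.000190 ± 0.00155, which is 3.01 SD above it. The simulated SD leaves out deviations that libraries share and may be too small, so this distance is uncertain. The slope over the 1648 FGF2 genes without near-identical copies was 0.0571 with a jackknife SE of 0.0708.

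**Figure D3:**
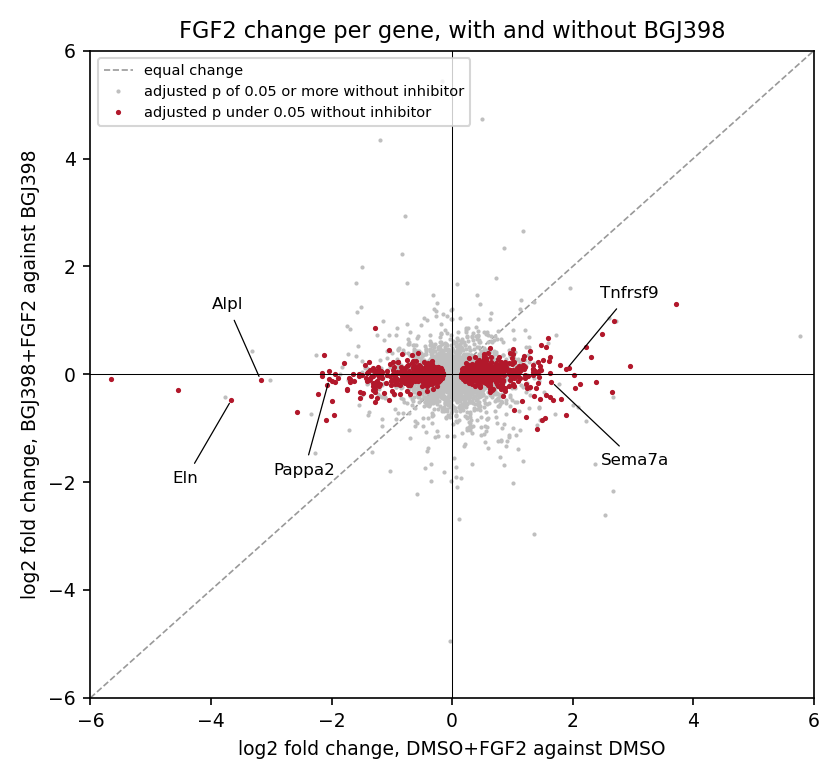
Log2 fold change of FGF2 without inhibitor (horizontal) and under BGJ398 (vertical) for 12525 genes, with 17 genes outside the axes. The labelled Alpl lies at −3.18 and −0.11 and Tnfrsf9 at 1.90 and 0.09.

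The third comparison asked what BGJ398 did when no FGF2 was added. Cholesterol synthesis and FGF feedback genes were lower. Of 23 cholesterol genes 6 fell and 0 rose, or 15 and 1 when adjusted over the list alone (adjusted p = 1.98e-26, and 0.00686 with an estimated correlation). The sterol sensor Insig1 changed by −0.48 ± 0.07, and the synthesis enzymes Fdps and Sqle by −0.38 ± 0.06 and −0.30 ± 0.05. Of 20 FGF and ERK feedback genes 3 fell and 0 rose, or 12 and 2 over the list alone (adjusted p = 3.19e-10, and 0.0321 with an estimated correlation). Etv5, a transcription factor downstream of FGF receptors, averaged 16.0 CPM in DMSO and 9.99 in BGJ398, a log2 fold change of −0.68 ± 0.10 (adjusted p = 0.00951), and the ERK pathway inhibitors Spred2 and Spred1 changed by −0.44 ± 0.08 and −0.35 ± 0.06. Dusp6 had −0.44 ± 0.13 (adjusted p = 0.249, or 0.0472 without the 3 libraries that deviated together), Etv4 −0.73 ± 0.23 (adjusted p = 0.312) and Spry4 −1.14 ± 0.37 (adjusted p = 0.345).

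Among the genes that rose, Prss35, a serine protease gene, was at 0.92 ± 0.12, Igfbp5, a binding protein of insulin-like growth factors, at 0.69 ± 0.07 and the surface glycoprotein Cd24a at 0.63 ± 0.06 (adjusted p = 0.000414), from 34.5 to 53.5 CPM. Alpl rose by 0.65 ± 0.10 (adjusted p = 0.0165) and the parathyroid hormone receptor Pth1r by 0.51 ± 0.09 (adjusted p = 0.0393). They were the 2 osteoblast genes of 18 that passed, with 0 lower (4 and 1 over the list alone), and the list had an adjusted p of 0.0497 (adjusted p = 0.326 with an estimated correlation), which was 0.155 without DMSO replicate 2, 0.129 without DMSO replicate 3, 0.185 without BGJ398 replicate 1 and 0.0513 with another scaling of the libraries. Matrix glycoproteins were called higher with 1 of 29 past the test, thrombospondin Thbs2 at 0.31 ± 0.06 (6 and 1 over the list alone; adjusted p = 0.00533; adjusted p = 0.0523 with an estimated correlation).

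YAP and SRF targets (0 of 19; 3 and 0 over the list alone; adjusted p = 0.326 with an estimated correlation), BMP and TGF-beta response genes (0 of 21; 4 and 0 over the list alone; adjusted p = 0.329 with an estimated correlation) and osteoclast regulators (1 of 23, Igfbp5; 5 and 1 over the list alone; adjusted p = 0.114 with an estimated correlation) were called higher. The glycolysis list was called lower with 0 of 26 members past the test and 1 lower over the list alone (adjusted p = 6.55e-10; adjusted p = 0.326 with an estimated correlation). In all, 5 lists were called higher and 3 lower for BGJ398 alone. Without BGJ398 replicate 1 these were 1 and 4, with the osteoblast, YAP and SRF, BMP and TGF-beta and osteoclast regulator lists lost, and without the 3 libraries that deviated together the same lists were lost. Without DMSO replicate 3 they were 2 and 3, with the osteoblast, BMP and TGF-beta and osteoclast regulator lists lost. Osteoclast regulators were also lost without BGJ398 replicate 2, from length-scaled TPM and with the within-group axis as a covariate, which also ended the osteoblast call, and matrix glycoproteins were lost from length-scaled TPM. Among 25 apoptosis regulators, which were not called as a list (adjusted p = 0.684), the anti-apoptotic Bcl2 fell, with a log2 fold change of −0.42 ± 0.07.

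In total 41 genes were called by edgeR for BGJ398 alone, 19 higher and 22 lower, with 2 changed at least 2-fold and 1037 at an unadjusted p under 0.05. Those 2 were higher and lay outside the rule for the largest named changes, whose highest was Prss35 at 0.92. The groups did not overlap for 2157 genes, 17.2% against the 10% chance gives. The count was 14 without DMSO replicate 1, 9 without DMSO replicate 2, 9 without DMSO replicate 3, 27 without BGJ398 replicate 1, 14 without BGJ398 replicate 2 and 11 without BGJ398 replicate 3. It was 153 by DESeq2, 83 with no filter, 12 from length-scaled TPM, 64 from these groups alone, 223 with length and GC offsets, 313 with the within-group axis as a covariate and 730 without the 3 libraries that deviated together. Of 29 genes named for this comparison only Prss35, Igfbp5, Cd24a and Jade2 passed an adjusted p of 0.05 in every fit tried.

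The fourth comparison asked what the inhibitor changed in cells given FGF2. Of the 1680 genes called for FGF2 alone, 1355 were called here with the opposite sign. Alpl went from 1.32 ± 0.24 to 17.4 ± 1.4 CPM (SD, n = 3), a log2 fold change of 3.71 ± 0.13 (adjusted p = 1.89e-09), Eln rose by 2.54 ± 0.24 and Col27a1 by 2.09 ± 0.16. Tnfrsf9 went from 121 to 33.5 CPM, a log2 fold change of −1.85 ± 0.11, Car9 from 635 to 178 CPM (−1.83 ± 0.12) and Cda changed by −1.82 ± 0.14. The glycolytic gene Tpi1 changed by −1.89 ± 0.50, and Rps12-ps3, at 13.84 ± 3.78, has near-identical copies elsewhere in the genome and is uncertain. FGF feedback genes were lower: 14 of 20 fell and 4 rose, or 15 and 4 when adjusted over the list alone (adjusted p = 1.64e-06; adjusted p = 0.0980 with an estimated correlation). Fosl1, a subunit of the AP-1 transcription factor, changed by −1.57 ± 0.14, Dusp4 by −1.65 ± 0.15, Etv4 by −1.25 ± 0.23, Etv5 by −0.85 ± 0.10 and Dusp6 by −0.80 ± 0.13. Spry4 changed by −1.24 ± 0.35 (adjusted p = 0.0221), with 0.0934 without DMSO+FGF2 replicate 3, 0.0913 without BGJ398+FGF2 replicate 1 and 0.0581 without BGJ398+FGF2 replicate 2.

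Of 18 osteoblast genes 10 rose and 1 fell, or 11 and 2 over the list alone (adjusted p = 1.74e-16, and 0.00105 with an estimated correlation). Sp7, the osteoblast transcription factor osterix, went from 8.94 to 25.4 CPM (1.51 ± 0.10), Sparc rose by 0.94 ± 0.05, and Spp1 was the gene that fell, from 957 to 316 CPM. Of 29 matrix glycoproteins 17 rose and 3 fell, or 18 and 3 over the list alone (adjusted p = 7.19e-26, and 4.88e-05 with an estimated correlation), with Postn at 1.61 ± 0.07, Tnc at 1.66 ± 0.08 and Fmod at 1.16 ± 0.05. Fibrillar collagens had 13 higher and 3 lower of 28 (15 and 4 over the list alone; adjusted p = 0.200 with an estimated correlation), with Col12a1 at 1.35 ± 0.13. Basement membrane genes had 8 and 2 of 19 (8 and 2; adjusted p = 0.256 with an estimated correlation), YAP and SRF targets 11 and 2 of 19 (11 and 2; adjusted p = 0.125 with an estimated correlation), BMP and TGF-beta response genes 11 and 4 of 21 (12 and 6; adjusted p = 0.166 with an estimated correlation) and FGF receptor genes 5 and 2 of 15 (7 and 4; adjusted p = 0.236 with an estimated correlation), the last at adjusted p = 0.0561 without BGJ398+FGF2 replicate 3. Fgfr2 rose by 1.01 ± 0.07 and Fgfr1 changed by −0.46 ± 0.06.

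Glycolysis and hypoxia genes had 0 higher and 22 lower of 26 (0 and 23; adjusted p = 0.166 with an estimated correlation), with the vasodilator peptide gene Adm at −2.67 ± 0.30. Unfolded protein response genes had 1 and 14 of 23 (1 and 14; adjusted p = 0.125 with an estimated correlation), with Hspa5 at −0.76 ± 0.07. Cholesterol genes had 1 and 8 of 23 (2 and 9; adjusted p = 0.294 with an estimated correlation), with Fdps at −0.38 ± 0.06. Interferon-stimulated genes had 1 and 9 of 23 (2 and 9; adjusted p = 0.236 with an estimated correlation), with Zbp1 at −1.96 ± 0.19 and Irf7 at −0.71 ± 0.12. The edgeR test called 2782 genes, 1355 higher and 1427 lower, 263 of them at least 2-fold, and 4368 genes (34.8% against 10% by chance) did not overlap between groups. The count was 1812 from length-scaled TPM, 1794 from these groups alone and 4591 with the within-group axis as a covariate.

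Of the genes called for FGF2 alone and for BGJ398 with FGF2, 1357 were shared and 1355 of them had opposite signs. FGF2 raised and BGJ398 lowered 768 of them, where independent lists would share 108, and 587 went the other way, where independent lists would share 78.9. These tests share the DMSO+FGF2 libraries, which enter with opposite signs, and the counts for independent lists leave that out. Simulations with no effect called 0.3 genes on average for FGF2. The 0 shared genes they gave on average were thus nearly fixed beforehand and are no measure of this overlap. The simulated correlation was −0.482, beside −0.663 observed. FGF2 and BGJ398 alone, which share the DMSO libraries, had a correlation of 0.285 beside 0.508 ± 0.0466 (SD) simulated with no effect, and a covariance of 0.0435 beside 0.0266 ± 0.0032. They shared 23 called genes, 13 with opposite signs and 10 with the same sign. Without genes that have near-identical copies the correlation was 0.0461 and the covariance 0.00304, below the 0.0153 ± 0.00215 simulated. The 3 DMSO libraries were too few to be split into parts of at least 2.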

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

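The corrections for gene length and GC content, and the use of the within-group axis as a covariate, were chosen after the results they test were seen; the test without the most abundant genes and the regroupings of libraries were planned earlier.

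The response to FGF2 differed between cells with and without BGJ398 for 532 genes by the test of the difference itself, and for 11 gene lists with the preset correlation, of which 2 stayed with an estimated correlation. The genes that stood out on the positive side were Eln at 3.19, Alpl at 3.07, Pappa2 at 1.95, Npnt at 1.82 and Col27a1 at 1.65, and on the negative side Tnfrsf9 at −1.80, Sema7a at −1.78, Hmga1 at −1.48, Msln at −1.39 and Cda at −1.38, all log2 interaction values. When the 12 libraries were regrouped at random into 4 groups of 3, 3 of 100 groupings, the real one included, gave at least 532 genes, with 1818 as the highest other, and 6 of 100 gave at least 11 lists, with 12 as the highest other. The 1818 came from a grouping that kept the 3 DMSO+FGF2 libraries together, which points to the structure of the samples, and a grouping that divided them gave 586. These splits decide nothing about chance, because the regrouping mixes the DMSO+FGF2 difference into the groups.

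For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 1680 genes for FGF2 without inhibitor and the highest other split 0, 2782 and 0 for BGJ398 with FGF2, 41 and 0 for BGJ398 alone, and 0 and 0 for FGF2 under BGJ398, where all 10 splits gave the same count. For lists the real and highest other values were 11 and 7, 12 and 10, 8 and 7, and 2 and 10 in the same order; 8 of the 10 splits of the libraries under BGJ398 gave at least 2 lists. Every other split mixes the compared groups, so a real difference would enter the spread and lower the gene calls. With the preset correlation mixed groups called lists too, but these calls may hold part of a real difference. These splits therefore decide nothing about chance either.

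The osteoblast and matrix lists were lower with FGF2. A trend with gene length or GC content was tested as the cause: with offsets that remove it in each library, all 90 tested members had a median log2 fold change of −0.326, beside −0.325 without them, and 51 fell and 9 rose, beside 46 and 9, which argues against that trend as the whole cause. The 46 that fell, a set picked for the pattern, went from −0.730 to −0.713. A loss of a few abundant transcripts was tested by leaving out the 10 genes with the most reads, and the median over the 86 members left was −0.317 with and without them. That removal moved the scaling very little, so the unchanged median by itself says little. The 10 genes with the most reads in each library took only 4.77% to 5.45% of its reads. The 10 genes left out took no more than that. A loss of such transcripts would raise, not lower, the read shares of the other genes. Leaving them out therefore could not test a fall of the members left and decides nothing. A response of the matrix program to FGF receptor signaling remains a hypothesis, found and tested on the same libraries, and for the collagen and basement membrane lists it also depends on the correlation assumed between genes.

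The glycolysis and hypoxia list was higher with FGF2, and the 3 libraries that deviated together from their groups made a library effect conceivable. With the within-group axis as a covariate the list's median was 0.484 with 22 of 26 genes past the test, beside 0.486 and 20 without it. That axis is centred on 0 within each group, so as a covariate it could hardly move a difference between groups. The unchanged median therefore decides nothing about a library effect. With length and GC offsets the median was 0.433 with 21 past the test, which argues against a length and GC trend as the whole cause. A difference in cell density or oxygen between the groups of cultures was not tested, and the list was not past the threshold with an estimated correlation.

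Reads of transcripts with no gene in the annotation used were 0.618% ± 0.0217 (SD, n = 3) of the DMSO+FGF2 libraries and 0.536% ± 0.0171 of the DMSO libraries, a difference in data that no comparison used. An exact permutation test, 2-sided, gave p = 0.1, the smallest that 3 against 3 libraries allow. In BGJ398 the share was 0.516% and in BGJ398+FGF2 0.541%. A single transcript without a name made up 35.4% of these reads in DMSO+FGF2 and 29.4% in DMSO.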

How the results depend on the processing

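The length and GC offsets, the within-group axis as a covariate, the fit without 3 libraries that deviated together, the fit without near-identical genes and the pooling of both inhibitor groups were chosen after the data were seen. Counts are given for FGF2 without inhibitor, FGF2 under BGJ398, BGJ398 alone, BGJ398 with FGF2 and the interaction, whose main values were 1680, 0, 41, 2782 and 532 genes; where no cause is named, the cause was not tested. RLE size factors, limma-voom, the CPM filter, protein-coding genes only and the fit without near-identical genes kept all 5 counts within 1.5 times. DESeq2 gave 5, 153 and 825 genes for FGF2 under BGJ398, BGJ398 alone and the interaction, and no filter 6 and 83 for the first pair of these. Length-scaled TPM gave 12 genes for BGJ398 alone (8 higher, against 19 of 41), 1812 for BGJ398 with FGF2 and 347 for the interaction. The 2 compared groups alone gave 1, 64 and 1794 genes for FGF2 under BGJ398, BGJ398 alone and BGJ398 with FGF2. Length and GC offsets gave 2670, 1, 223 and 1235 genes for FGF2, FGF2 under BGJ398, BGJ398 alone and the interaction, the within-group axis 3373, 1, 313, 4591 and 1642 in the order above, and the fit without 3 libraries 2611, 4, 730 and 1038 for all but BGJ398 with FGF2. The within-group axis was taken from the residuals of the same libraries, so the rise in counts with it follows from its construction. Both inhibitor groups together gave 155. Stricter thresholds lower counts by construction: 874, 10, 1400 and 225 genes had an adjusted p under 0.01 and 176, 2, 263 and 108 changed at least 2-fold, for all but FGF2 under BGJ398.

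Leaving out 1 library gave 1018 to 1336, 0 to 1, 9 to 27, 1948 to 3345 and 328 to 956 genes, and 11 to 12, 0 to 6, 5 to 11, 12 to 13 and 10 to 13 lists; 2 libraries then stand for a group. The slope of the FGF2 change under BGJ398 ranged from −0.0700 (without BGJ398+FGF2 replicate 2) to 0.0596, was −0.0300 without DMSO replicate 2 and −0.0190 with no filter, so its sign is not determined (jackknife SE 0.122), and the correlation of FGF2 with BGJ398 alone from 0.220 to 0.458. The main list counts of 11, 2, 8, 12 and 11 became 2, 0, 2, 2 and 2 with an estimated correlation and 17, 0, 4 and 22 by fry for the first 4, 1 from length-scaled TPM for FGF2 under BGJ398, and 5 without 3 libraries for BGJ398 alone. Without near-identical genes the correlation was 0.0466. No called gene among the named ones, and no list called in the main fit, turned its direction. Other called genes were not followed. Single named genes kept their side of the threshold in 7374 settings, lost it in 408 and gained it in 6. Of the named genes called for FGF2, 13 of 113 were lost in some setting. For BGJ398 alone this held for 25 of 29, for BGJ398 with FGF2 for 15 of 117 and for the interaction for 22 of 89. Single called lists kept it in 651 and lost it in 75.

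Replicate numbers did not pair the libraries: of 18 pairs with the same number 8 had a correlation of deviations over 0.1 (−0.661 to 0.720, mean −0.00979, beside 0.0250 for other numbers). The replicate block gave 1503, 0, 21, 2565 and 428 genes, 12, 2, 8, 12 and 12 lists, a slope of 0.0418 and a correlation of 0.296. The within-group axis held 64.0% of the within-group variance and correlated with log2 gene length across genes at −0.791. Depth limits low genes: Spry4 had 216 and Bglap 167 reads in all 12 libraries.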

Other observations

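The comparison of both inhibitor groups with DMSO, the genes named in the first 3 paragraphs and the tests of shared DMSO libraries, with their choice of genes, were chosen after the data were seen.

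Taken as 1 group of 6 libraries, the BGJ398 and BGJ398+FGF2 cultures differed from the 3 DMSO libraries in 155 genes, 79 higher and 76 lower by edgeR, including 40 of the 41 genes called for BGJ398 alone. Cholesterol synthesis genes fell in 10 of 23 cases with 0 higher (adjusted p = 0.00271 with an estimated correlation), among them Hmgcs1 at −0.40 ± 0.05. FGF and ERK feedback genes fell in 6 of 20 cases with 0 higher (adjusted p = 0.0113 with an estimated correlation), with Dusp6 at −0.49 ± 0.11 and Etv4 at −0.85 ± 0.20, which had not passed for BGJ398 alone, Etv5 at −0.70 ± 0.08 and the AP-1 subunit gene Fosl1 at −0.65 ± 0.12. Spry4 did not pass here either. The highest fitted changes were those of the processed pseudogenes Gm12918 at 13.54 ± 2.67 and Gm10221 at 9.51 ± 0.95, with 12.98 and 8.58 for FGF2. How much of their sequence other genes share is not given here, so these changes are uncertain. Higher protein-coding genes included Lrrc15 at 0.96 ± 0.20, a membrane protein of matrix-forming cells, and Smpd3, a sphingomyelinase needed for bone mineral, at 0.85 ± 0.18. Angptl4 was at 0.80 ± 0.15 and Alpl at 0.59 ± 0.09. Of the 84 splits of these 9 libraries only the real one gave as many genes, 1 of 84, with 2 genes in the highest other split. Since the comparison was chosen after the calls for BGJ398 alone were seen on the same libraries, this does not exclude chance.

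With the preset correlation 8 of 27 lists were called in this comparison. Beside the cholesterol and feedback lists, matrix glycoproteins had 5 higher and 1 lower of 29 (adjusted p = 0.0610 with an estimated correlation), osteoclast regulators 4 and 1 of 23 (adjusted p = 0.0610 with an estimated correlation), BMP and TGF-beta response genes 3 and 0 of 21 (adjusted p = 0.393 with an estimated correlation) and YAP and SRF targets 2 and 0 of 19 (adjusted p = 0.362 with an estimated correlation). Interferon and glycolysis lists were called lower with 0 members past the test (adjusted p = 0.396 and 0.428 with an estimated correlation). Eln was lower with FGF2 (−3.66) and also lower in the inhibitor groups (−0.87 ± 0.18, adjusted p = 0.0292), 2 comparisons that share the DMSO libraries.

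Further FGF2-responsive genes lay below the expression level set for named genes. Sprr1a, a gene of cornified epithelia that is also induced by injury, averaged 0.734 CPM in DMSO, 5.62 in DMSO+FGF2, 0.263 in BGJ398 and 0.292 in BGJ398+FGF2, with an FGF2 change of 2.95 ± 0.24. The cytokine gene Il33 rose by 2.69 ± 0.46, from 0.283 to 1.88 CPM. The collagen-processing enhancer Pcolce2 and the microfibril protein Mfap4 changed by −2.16 ± 0.26 and −2.04 ± 0.24, from 3.61 to 0.80 and from 3.39 to 0.831 CPM, and the basement membrane collagen Col15a1 by −2.12 ± 0.39.

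A hypothesis from the design is that FGF receptors were already active before FGF2 was added, so that BGJ398 alone would move genes the way it does with FGF2 present. Over the 2782 genes called for BGJ398 with FGF2, the slope of the change without FGF2 on it, which shares no library, was 0.216 and stayed above 0 without each library in turn (0.112 to 0.292), the bound set beforehand. Its jackknife SE was 0.202. The 2 comparisons had 33 called genes in common, 15 higher and 16 lower in both where independent lists would share 2.05 and 2.50, and 77.3% of the 2782 genes had the same sign. Without near-identical genes it was 0.168 (SE 0.0428), over genes with a mean of at least 5 CPM 0.279 (SE 0.307, 0.0697 to 0.442), and with both limits 0.185 (SE 0.0617), so the precision depends on which genes are kept. The genes called in both mostly moved the same way, as the hypothesis needs, but the slope over all 2782 lies about 1 SE from 0, and an action of BGJ398 on other targets stays open too, since only 1 inhibitor was used.

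If BGJ398 alone moved genes opposite to FGF2, their covariance would lie below what the shared DMSO libraries give. Over all genes it was 0.0435, above the simulated 0.0266 ± 0.00320 (SD), which fits neither outcome. Over 11882 genes without near-identical copies it was 0.00304, below the simulated 0.0153 ± 0.00215 (SD). The simulation gave all groups the same spread. The DMSO libraries differed from each other by Poisson ratios of 5.19 to 6.10, and those of BGJ398+FGF2 by up to 25.5. The simulated covariance may thus be too high, and the lower observed value decides nothing. In 2 other gene sets the covariance was 0.0154 over genes of at least 5 CPM and −0.000591 with both limits. The sign of the difference changed when near-identical genes were left out, for which reads may be divided differently between libraries, and is no firm evidence.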
